A study of Homo sapiens with 12 samples.

How the data were processed

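RNA was measured in 12 libraries of PPRE-eGEP-THP-1 cells, 3 for each of 4 groups. Per the labels' protocols, cells were differentiated with phorbol 12-myristate 13-acetate at 25 ng/mL for 48 h and rested for 24 h. They were then polarized for 24 h with lipopolysaccharide (100 ng/mL) and interferon gamma (20 ng/mL) for M1, or interleukin 4 and interleukin 13 (20 ng/mL each) for M2, with 100 µM MCHP or solvent. Total RNA was extracted with TRIzol, mRNA was purified on poly-T beads and libraries were made from randomly primed cDNA, per the labels' protocols. The labels do not expand PPRE and give no batch, date or strand setting.

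The deposited table holds raw counts per gene for all 12 libraries, whole numbers with no normalization, beside the length of each gene model, per the file headers. The submitters' processing notes name the build hg38, fastp, HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with no roles or order. The table has 58907 genes, of which 172 are unannotated models and 26650 had no count in any library. Its other 58735 identifiers, with chromosome, start and end, matched GENCODE release 29. Coordinates are given as the table gives them.

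Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr over the 4 groups, which left 15252 genes and at least 99.8% of the counts of each library. Libraries were scaled with TMM factors, and all 12 were fitted together with 1 mean per group, leaving 8 residual degrees of freedom. Contrasts were tested with the quasi-likelihood F-test (two-sided), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05 on the adjusted p. The 4 contrasts were MCHP against DMSO in M1 and in M2, the difference of these (M1 minus M2), and M1 against M2 in DMSO. Standard errors were derived from the F statistic and the log2 fold change. CPM are TMM-scaled, given as the mean and SD of 3 libraries.

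A total of 39 gene lists, with 809 genes, was written from general knowledge, and 1 of these genes had no match. Lists were tested with camera on the same fit, with a preset correlation of 0.01 between genes, a minimum of 5 tested members, which 35 lists reached, and Benjamini-Hochberg adjustment over lists. The test was repeated with the correlation estimated from the data. With it, the calls that held were the PPAR targets in the 3 MCHP contrasts and 9 of 14 lists between M1 and M2. The overlap of both responses was tested with Fisher's exact test among the genes tested. Lists, contrasts, tests, the choice of named genes and most alternatives were fixed before the data were examined.

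Named genes were the 10 with the largest change in each direction among called protein-coding genes with a symbol, a mean of at least 5 CPM and groups that did not overlap. To these were added up to 4 members with the smallest p of each list that camera called or that had at least 3 called members, and a fixed set of PPAR, lipid and polarization genes. The non-overlap condition was left out for the difference of responses. TYROBP, IL10RA, FGR, PODXL and GPC1 in M2, CD86 in M2, CD163 between M1 and M2, and the difference for CD36, ACSL5, MT-RNR2 and 3 pseudogenes were named after their values were seen. PDK4, in the fixed set, had no counts.

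Depth was 14352202 to 16871233 counts per library. Where a group had no count for a gene, a floor of 3 counts over the group was used. Ratios at low counts have exact 95% binomial intervals; intervals and floors cover counting error only. Reads shared with near-identical copies make FABP5, GBP1, ALDOA, the HLA genes, the chemokine paralogs and MT-CO1 uncertain. Since no strand setting is given, reads of overlapping or antisense genes could not be told apart.

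The steps were tested on simulated counts for 15252 genes with 200 changed. At folds of 1.5, 2 and 4 they recovered 55.2%, 76.1% and 92.4% of changed genes in the M1 contrast, 62.7%, 71.6% and 93.9% in M2, and 25.4%, 68.7% and 81.8% in the difference. Of all calls, 5.10%, 6.75% and 7.87% were false. With only the PPAR targets raised 1.5-fold in M2, camera with the preset correlation called that list and 2 others of the 35, which share members with it: fatty acid oxidation (7 of 25) and markers of lipid-associated macrophages (4 of 22). Simulated genes were drawn independently of each other. The simulation therefore cannot show how often the preset correlation calls lists falsely where genes vary together. All simulated libraries also had the same spread per gene, so none stood apart as M2 DMSO replicate 1 did in the data. The recovered and false shares need not hold where such a library is present.

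Alternatives were the size factors of DESeq2, library size alone, no filter on low counts, a block on replicate number, DESeq2 1.42.0, limma-voom (limma 3.58.1), a minimum log2 fold change of 1, protein-coding genes only, a fit of the compared libraries only, and each library of the groups compared left out in turn. GC-corrected offsets (a loess line with a span of 0.5), sample quality weights, the M1 contrast without M2 DMSO replicate 1, protein-coding genes only for single genes, and fits of the compared libraries for single and shared genes were added after the data were seen. Replicate numbers were not used as pairs, since after removal of group means 0 of 18 correlations between libraries with the same number passed 0.1.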

Results

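Polyadenylated RNA was sequenced from PPRE-eGEP-THP-1 cells, a derivative of the human monocytic leukaemia line THP-1, after differentiation into macrophages with phorbol ester. The cells were then polarized for 24 h toward M1 with lipopolysaccharide and interferon gamma, or toward M2 with interleukins 4 and 13. During polarization they received 100 µM monocyclohexyl phthalate (MCHP, the monoester of the plasticizer dicyclohexyl phthalate) or the solvent DMSO. The 4 groups, M1 with MCHP, M1 with DMSO, M2 with MCHP and M2 with DMSO, held 3 libraries each, which the labels call biological replicates. Each library held 14352202 to 16871233 gene counts, and 15252 genes passed the filter on low counts. Polarization took up the first principal component of the 12 libraries, with 71.2% of the variance. M2 DMSO replicate 1 stood apart from its group: over genes, its log2 deviation from the mean of the other libraries of the group had an SD of 0.318, against 0.119 to 0.193 for the other 11 libraries.

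The comparison of MCHP with DMSO in M2 cells asked how the compound regulates alternatively polarized macrophages, the series being about macrophage polarization and lipid metabolism. Genes of fatty acid binding and lipid storage were among those that rose. FABP4, a fatty acid binding protein of adipocytes and macrophages (ENSG00000170323, chromosome 8, 81478419 to 81483263, hg38), went from 8.30 ± 4.46 to 91.8 ± 13.8 CPM (counts scaled to library size with TMM factors; SD, n = 3), a log2 fold change of 3.48 ± 0.21 (SE). PLIN2, which coats lipid droplets (ENSG00000147872, chromosome 9, 19108375 to 19149290), rose from 48.3 ± 2.64 to 148 ± 7.63 CPM, by 1.61 ± 0.07. CD36, a scavenger and fatty acid receptor (ENSG00000135218, chromosome 7, 80369575 to 80679277), rose from 136 ± 21.5 to 293 ± 1.22 CPM, by 1.10 ± 0.08. Among those that fell was the chemokine gene CCL1 (ENSG00000108702, chromosome 17, 34360328 to 34363231), which went from 275 ± 50.7 to 113 ± 11.3 CPM, a log2 fold change of -1.28 ± 0.10. Adjusted p by edgeR's quasi-likelihood test was 2.2e-08 for FABP4, 3.9e-10 for PLIN2, 3.1e-07 for CD36 and 7.6e-07 for CCL1, and each of these calls held under every alternative run on it, a log2 change of at least 1 among them.

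Of the 26 tested members of the list of PPAR (peroxisome proliferator-activated receptor) target genes, 14 rose and none fell in M2 over all genes, against 18 and 1 adjusted over the list alone. The median log2 fold change of the list was 0.31 (camera adjusted p = 2.9e-32, and adjusted p = 3.2e-05 with an estimated correlation). Besides FABP4, PLIN2 and CD36, its members included HILPDA, an inhibitor of triglyceride breakdown (1.27), NR1H3, which encodes the sterol receptor LXR alpha (0.85), ANGPTL4, an inhibitor of lipoprotein lipase (0.61, adjusted p = 0.019), and HADHA of mitochondrial fatty acid oxidation (0.60). ANGPTL4 was no longer called without M2 MCHP replicate 2 (adjusted p = 0.074) or 3 (0.067). The receptor gene PPARG itself was at -0.19 (adjusted p = 0.34), PPARA at 0.04, PPARD at -0.11 and the target CPT1A at 0.37 (adjusted p = 0.059), none of them called.

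Of 4 further lists of lipid metabolism, 3 were called higher by camera with smaller medians. Cholesterol synthesis and uptake was not called (median 0.08, adjusted p = 0.19, but 0.035 without a filter on low counts), with 1 of 26 members higher over all genes and adjusted over the list alone. For fatty acid oxidation, 4 of 25 tested members rose and HADH fell, by 0.43, with 8 and 1 adjusted over the list alone (median 0.10, camera adjusted p = 0.0018, but adjusted p = 0.081 with an estimated correlation). Of these 25 members, 7 are also on the PPAR target list. For fatty acid synthesis and desaturation, 3 of 20 rose, among them DGAT2, which makes triglycerides (0.59), and the desaturase SCD (0.46), with 4 adjusted over the list alone (median 0.10, adjusted p = 0.00076, but adjusted p = 0.097 with an estimated correlation). For targets of LXR, 4 of 14 rose, over all genes and adjusted over the list alone: NR1H3, the lipoprotein receptor SCARB1 (0.70), SCD and the cholesterol exporter ABCA1 (0.35). That list had a median of 0.02 (adjusted p = 8.3e-05, but adjusted p = 0.097 with an estimated correlation). Of 13 tested mitochondrially encoded transcripts 9 rose, such as MT-ND5 (0.46), MT-CYB (0.45) and MT-ATP6 (0.44), with 11 adjusted over the list alone (median 0.39, adjusted p = 1.4e-11, but adjusted p = 0.097 with an estimated correlation). Beside this, the mitochondrially encoded share of all counts was 3.88% ± 0.35 (SD, n = 3) with MCHP and 3.15% ± 0.07 with DMSO. The size leans on M2 MCHP replicate 3, at 4.28% against 3.64% and 3.71% in replicates 1 and 2. With DMSO the share was 3.10% to 3.23%.

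Markers of lipid-associated macrophages split in M2. Over all genes, FABP4, PLIN2, FABP5 (1.23) and CD36 rose, while the lipid-sensing receptor gene TREM2 (-0.44, adjusted p = 0.0080) and its adaptor TYROBP fell. Of these 4 that rose, 3 are also on the PPAR target list. Adjusted over the list alone, 5 of 22 members rose and 6 fell. The median was -0.06, whereas the mean was 0.14 and camera called the list higher (adjusted p = 0.00018, but adjusted p = 0.24 with an estimated correlation and 0.17 without a filter on low counts). CD9 (-0.29, adjusted p = 0.078), GPNMB (-0.35, 0.15) and SPP1 (-0.08, 0.59) were not called. TREM2 was no longer called without M2 MCHP replicate 1 (adjusted p = 0.057).

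Some polarization markers of both kinds fell with MCHP in M2, and others rose. Of 16 tested M2 markers, 5 fell, including CCL13 (-1.32), CLEC10A (-0.99) and the lectins CD209 (-0.59) and CLEC7A (-0.49), while the chemokine CCL22 rose from 742 to 1214 CPM (0.71). Adjusted over the list alone, 8 fell and 1 rose (median -0.42, adjusted p = 0.00011, but adjusted p = 0.097 with an estimated correlation). Of 25 M1 markers, 8 fell, including CCL8 (-1.05), TNFSF10 (-0.79), the Fc receptor FCGR1A (-0.63) and CCL5 (-0.35), and PTGS2 and CD86 rose, with the same counts adjusted over the list alone (median -0.10, adjusted p = 0.0063, but adjusted p = 0.24 with an estimated correlation and 0.054 without a filter on low counts). Of 27 NF-kB cytokines and chemokines, 6 fell, including CCL2 (-0.81) and CCL7 (-0.58), and the cyclooxygenase gene PTGS2 rose (0.51), with 9 and 2 adjusted over the list alone (median -0.14, adjusted p = 0.00083, but adjusted p = 0.24 with an estimated correlation). The size for CCL2 leans on M2 DMSO replicate 1, with 1939 counts against 1278 and 1277 in replicates 2 and 3. With MCHP it held 643 to 1027. Markers of dendritic cells included CD83, which fell by 0.60, and CLEC10A, the 2 that fell among 9 tested. Adjusted over the list alone 4 fell (median -0.28, adjusted p = 0.0020, but adjusted p = 0.10 with an estimated correlation). CLEC10A was no longer called by limma-voom (adjusted p = 0.073) or without M2 MCHP replicate 1 (0.058) or 3 (0.17) or M2 DMSO replicate 3 (0.069).

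The type I interferon response list was called lower with MCHP in M2, with 4 of 30 members called, among them IFIT2 (-0.61) and IRF9 (-0.84), and 6 adjusted over the list alone (median -0.18, camera adjusted p = 0.00045, but adjusted p = 0.49 with an estimated correlation). This rested on 1 library: without M2 DMSO replicate 1 the median was -0.01, the adjusted p was 0.75, and 4 members rose and 4 fell. In that library 27 of the 30 members were higher than in the mean of M2 DMSO replicates 2 and 3, by a median of 0.52 on the log2 scale. IRF9 was also no longer called without M2 DMSO replicate 1 (adjusted p = 0.084) or without M2 MCHP replicate 1 (0.13) or 3 (0.16).

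Outside the lists above, the largest rises in M2 included GPD1, an enzyme of glycerol phosphate synthesis (1.68 ± 0.15), SHANK3 (1.44), TLR4, the receptor for lipopolysaccharide (ENSG00000136869, chromosome 9, 117704175 to 117724730; 1.42 ± 0.07), VWA5A (1.39), the transporter SLCO2B1 (1.38) and MEGF9 (1.26). The largest falls included the chemokine receptor CX3CR1 (-1.14), TOGARAM2 (-0.97), the hyaluronan synthase HAS3 (-0.94) and the nuclear receptor NR4A2 (-0.91). The transporter gene ABCG2 held 75 counts with MCHP and 11 with DMSO over 3 libraries each, a ratio of 7.26 (95% counting interval 3.84 to 15.2).

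In all, edgeR's quasi-likelihood test called 779 of 15252 genes changed by MCHP in M2 at an adjusted p under 0.05, 446 higher and 333 lower, 50 of them by at least 1 on the log2 scale. With library size as the only scaling the split was 306 higher and 465 lower of 771, so the balance of directions depended on the scaling. The count was 386 without M2 MCHP replicate 1, 393 without M2 MCHP replicate 3, 1747 without M2 DMSO replicate 1 and 177 in a fit of the 6 M2 libraries alone. In that fit ANGPTL4, MT-ND5, MT-CYB, MT-ATP6, ABCA1, CLEC10A, CCL8, CCL2, CCL7, PTGS2, IFIT2 and IRF9 were no longer called (adjusted p = 0.051 to 0.22).

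**Figure D1:**
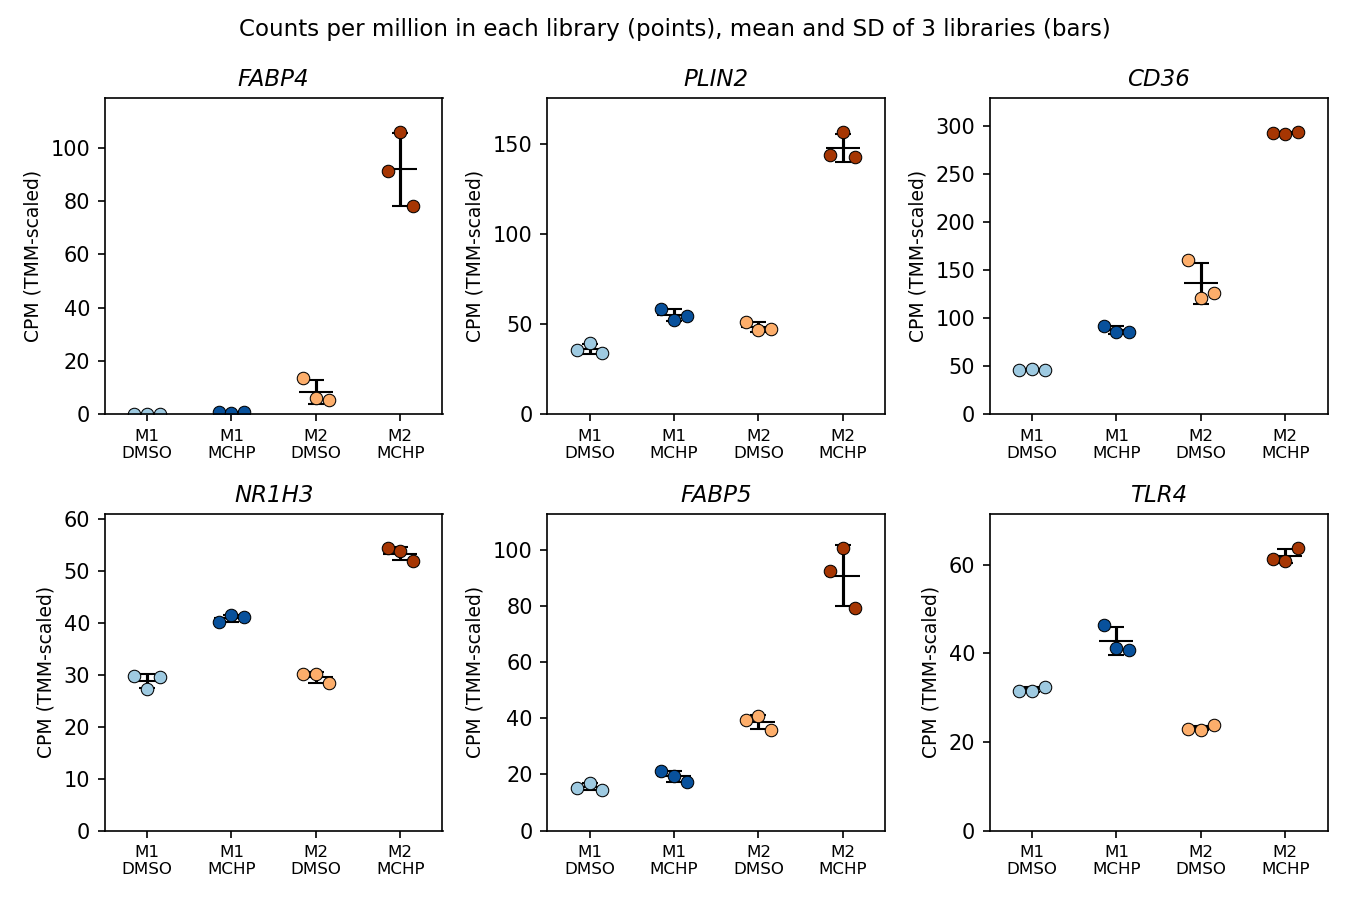
CPM in each of the 12 libraries (points) with the mean and SD of 3 libraries per group (bars) for FABP4, PLIN2, CD36, NR1H3, FABP5 and TLR4. FABP4 went from 8.30 CPM with DMSO to 91.8 CPM with MCHP in M2. In M1 it went from 0.13 to 0.66 CPM, at the limit of the depth.

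The comparison of MCHP with DMSO in M1 cells asked the same of classically activated macrophages, and few genes passed the test. CD36 went from 46.7 ± 0.69 to 88.0 ± 3.91 CPM (SD, n = 3), a log2 fold change of 0.91 ± 0.09 (adjusted p = 7.4e-05). PLIN2 rose 1.51-fold from 36.4 ± 2.81 CPM (0.60 ± 0.08, adjusted p = 0.0030) and NR1H3 rose from 28.8 to 40.9 CPM (0.50 ± 0.07, adjusted p = 0.0077). The proteoglycan gene GPC1 (ENSG00000063660, chromosome 2, 240435671 to 240468078) rose from 4.37 to 9.65 CPM (1.14 ± 0.17, adjusted p = 0.0083). Also higher were SHANK3 (0.71), VIPR2 (0.50), FGR (0.43), TLR4 (0.43), PODXL (0.38), MMP19 (0.35) and the stress-induced factor ATF3 (0.32). ALAS1, the first enzyme of heme synthesis, fell by 0.35 and the interleukin 10 receptor gene IL10RA fell by 0.32. FABP4 was at the limit of the depth here, with 30 counts over 3 libraries with MCHP and 6 with DMSO, a ratio of 4.95 (95% counting interval 2.03 to 14.5) that did not pass the test (adjusted p = 0.88).

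Among the PPAR targets in M1, CD36, PLIN2 and NR1H3 rose over all genes, and 5 rose and 1 fell adjusted over the list alone (median 0.12, camera adjusted p = 5.7e-11, and adjusted p = 0.0017 with an estimated correlation). PPARG was at -0.36 (adjusted p = 0.64), LPL at -0.32 (0.19) and TREM2 at -0.51 (0.26), none of them called. PPARG passed in M1 without M2 DMSO replicate 1 (0.017), and LPL did too (0.0032).

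The next 6 lists that camera called in M1 had small medians, and each call was lost with an estimated correlation. Type I interferon genes were higher (median 0.11, adjusted p = 1.7e-05, but adjusted p = 0.47 with an estimated correlation), with none of 30 called over all genes and 1 higher adjusted over the list alone. NF-kB cytokines and chemokines were higher (median 0.07, adjusted p = 0.0017, but adjusted p = 0.31 with an estimated correlation), with none of 27 called and 4 higher adjusted over the list alone. The integrated stress response was higher (median 0.07, adjusted p = 0.0011, but adjusted p = 0.28 with an estimated correlation), with ATF3 called on both counts among 29. Oxidative phosphorylation was lower (median -0.07, adjusted p = 0.00012, but adjusted p = 0.31 with an estimated correlation), with none of 43 called on either count. Glycolysis was lower (median -0.08, adjusted p = 4.0e-04, but adjusted p = 0.28 with an estimated correlation), with none of 22 called and 2 lower adjusted over the list alone. Monocyte markers were lower (median -0.17, adjusted p = 0.0020, but adjusted p = 0.091 with an estimated correlation and 0.096 without a filter on low counts), with none of 8 called and 3 lower adjusted over the list alone.

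In all, edgeR's quasi-likelihood test called 13 of 15252 genes changed by MCHP in M1, 11 higher and 2 lower, where 817 had an unadjusted p under 0.05. With any 1 of the 6 M1 libraries left out, 1 to 4 genes were called, and CD36 was the only one of the 13 called under every alternative other than a log2 change of at least 1, which left GPC1 alone. The count was 160 without M2 DMSO replicate 1, a library outside this comparison that shares the spread estimate, and 287 in a fit of the 6 M1 libraries alone, and both included all 13.

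**Figure D2:**
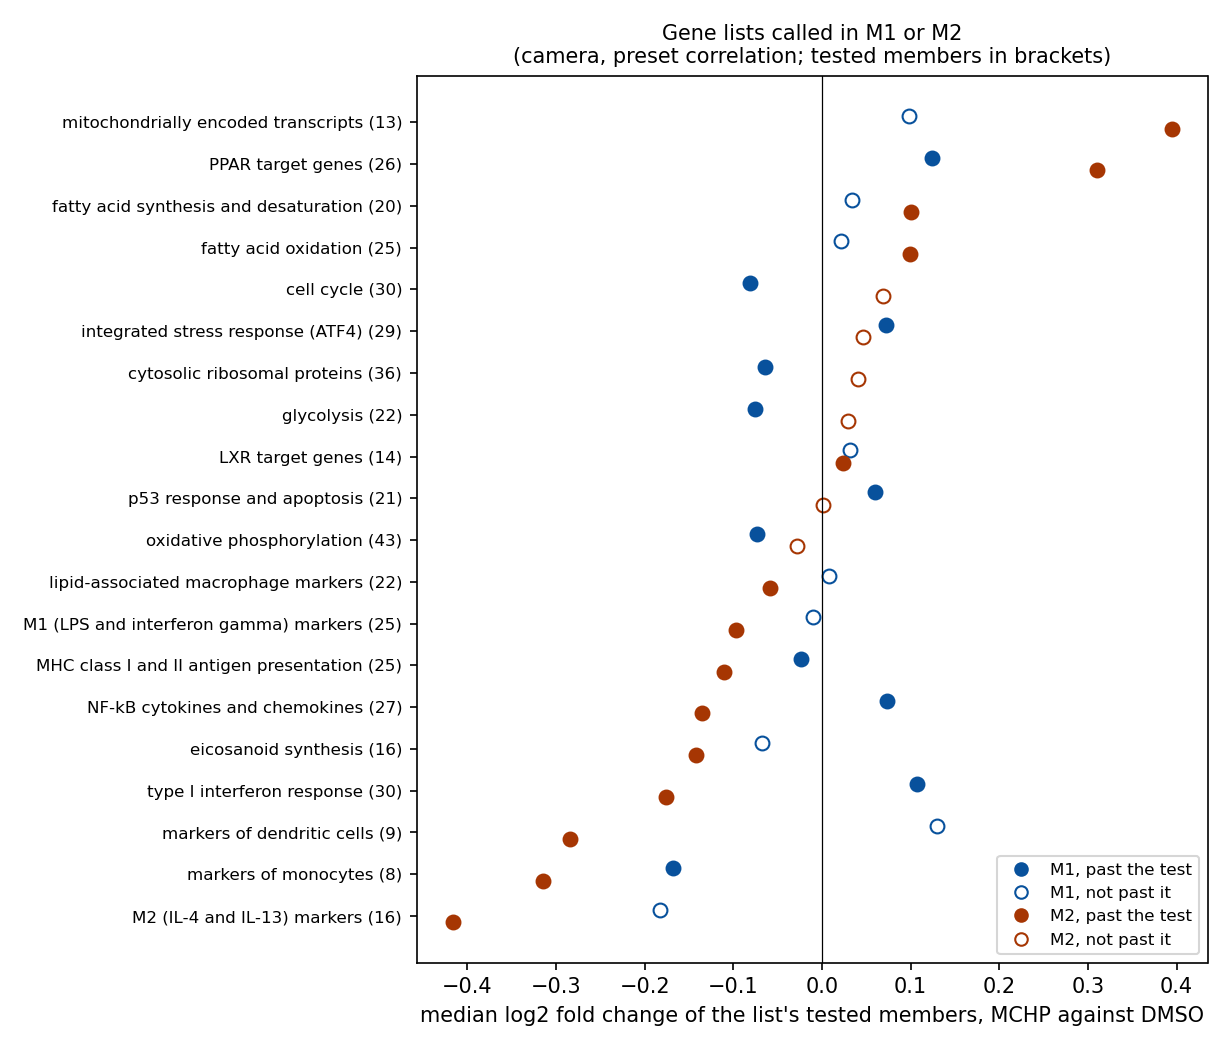
Median log2 fold change, MCHP against DMSO, of the tested members of each gene list that camera called in M1 or M2 with its preset correlation (filled points, called; open points, not called). PPAR targets lay at 0.31 in M2 and 0.12 in M1, and only this list was called in both with an estimated correlation.

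The difference between these responses was tested as its own contrast, M1 minus M2. Several lipid genes had smaller responses in M1: the difference was -1.02 ± 0.11 for PLIN2 (adjusted p = 0.00015), -1.19 ± 0.16 for the fatty acid binding protein FABP3 (0.0030), -0.92 for FABP5 (0.012), -0.65 for SCARB1 and -0.48 for HADHA (0.019 each). For CD36 (-0.19, adjusted p = 0.69) and NR1H3 (-0.35, 0.25) the difference was not called. Nor was it called for FABP4, which had few counts in M1. TLR4 (-0.99 ± 0.10, adjusted p = 0.00015), the amine oxidase gene AOC3 (-1.24) and the adhesion receptor gene ADGRE3 (-0.85) differed the same way. Immune genes that were lower with MCHP in M2 lay higher on this contrast: CCL8 (1.01, adjusted p = 0.022), CCL1 (0.78, 0.031), CD209 (0.77 ± 0.11, 0.0030), IFIT2 (0.71, 0.022) and CD83 (0.57, 0.0083). For the PPAR targets, 3 of 26 differed over all genes and 6 adjusted over the list alone, all lower in M1 (median -0.23, camera adjusted p = 2.0e-09, and adjusted p = 0.0032 with an estimated correlation). Type I interferon genes lay higher on the contrast (median 0.29, adjusted p = 2.0e-09, but adjusted p = 0.24 with an estimated correlation), with 1 of 30 called and 5 adjusted over the list alone. Their median was 0.06 without M2 DMSO replicate 1 (adjusted p = 0.0085). The mitochondrially encoded transcripts lay lower (median -0.32, adjusted p = 4.2e-08, but adjusted p = 0.19 with an estimated correlation), with none of 13 called and 9 adjusted over the list alone.

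In all, 25 genes differed in their MCHP response by edgeR's quasi-likelihood test, 9 with a positive difference and 16 with a negative one. This count was 385 without M2 DMSO replicate 1 and between 6 and 13 without any 1 of the M1 libraries, M2 MCHP replicate 1 or M2 MCHP replicate 3. PLIN2 and FABP3 were called under every alternative run, and TLR4, ADGRE3, CD209 and CD83 under every one other than a log2 change of at least 1.

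The overlap of both responses was small in number but shared its direction. Of the 11 genes that rose in M1, 9 also rose in M2, where 0.32 was the number for independent responses (Fisher's exact test, one-sided, p = 7.5e-13): CD36, PLIN2, NR1H3, TLR4, SHANK3, GPC1, FGR, PODXL and MMP19. Both genes that fell in M1, ALAS1 and IL10RA, also fell in M2 (Fisher's exact test, p = 0.00048), and no gene was called in opposite directions. These tests treat genes as independent and equally likely to be called. Both contrasts share the spread estimate of each gene, so 0.32 may be too low and the p-values too small. Across all 15252 tested genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.11 and a Spearman rho of 0.16. Among the 779 genes called in M2, r was 0.50 and rho 0.56, and 78.8% had the same sign in M1. Without M2 DMSO replicate 1, 113 genes were shared in direction and 4 were opposite. With GC-corrected offsets, 2 genes called lower in M1 were called higher in M2. With any 1 of the M1 libraries left out 1 to 4 were shared, and without M2 MCHP replicate 1, 2 or 3 the number was 4, 6 or 7.

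**Figure D3:**
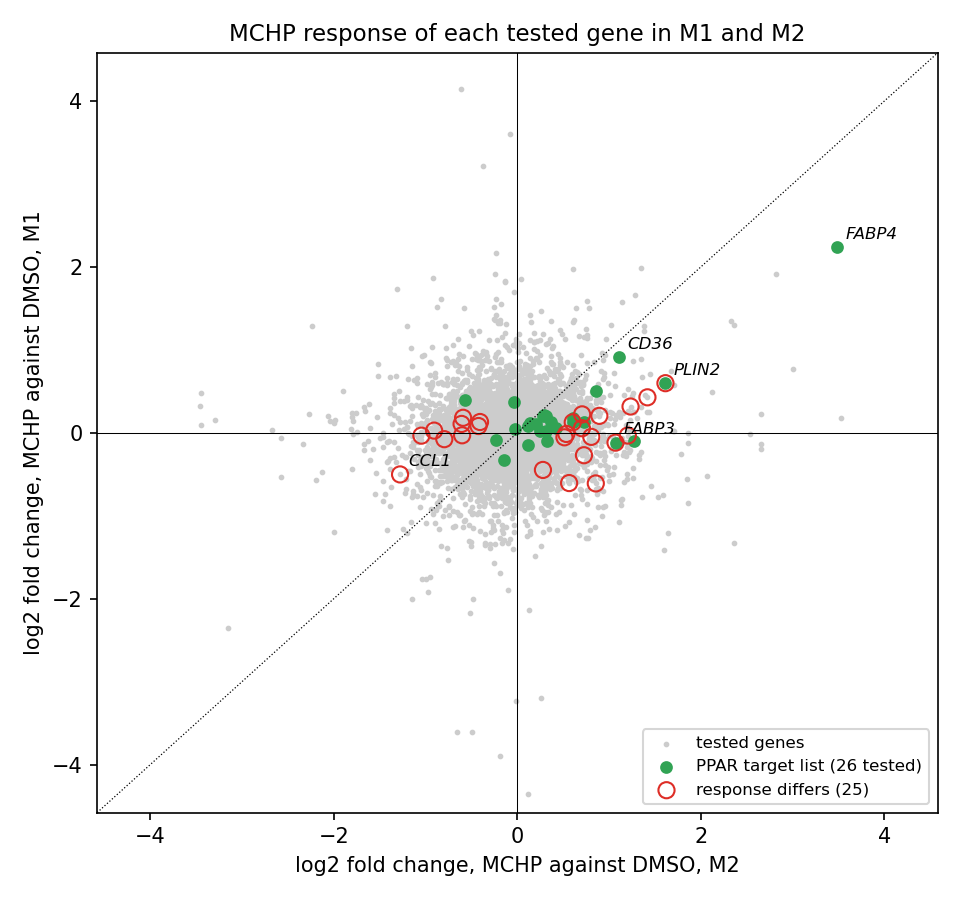
Log2 fold change with MCHP against DMSO in M2 (x axis) and M1 (y axis) for the 15252 tested genes, with the 26 PPAR targets in green, the 25 genes whose response differed circled, and the line of equal response dotted. Of the 26 PPAR targets 22 had a larger value in M2 than in M1.

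The comparison of M1 with M2 in DMSO showed how far the polarized cells lay from each other. Without a group of unpolarized cells, it cannot tell which of them had moved. Several interferon-induced genes had almost no counts in M2. IDO1, which degrades tryptophan (ENSG00000131203, chromosome 8, 39902275 to 39928444), was at 224 ± 10.3 CPM (SD, n = 3) in M1 and had no count in M2, at least 3763-fold higher by a floor of 3 counts over the group. On the same floor the guanylate-binding protein gene GBP4 was at least 1819-fold and the chemokine gene CXCL9 at least 1808-fold higher. The chemokine CXCL10 went from 0.48 to 348 CPM (9.49 ± 0.13, a ratio of counts of 731 with a 95% counting interval of 491 to 1141) and the T cell costimulator CD80 from 0.08 to 2.02 CPM, with 90 counts in M1 and 4 in M2 (ratio 25.5, interval 9.61 to 95.5), while the inflammatory cytokines TNF (1.31) and IL1B (0.89) differed less. Higher in M2 were CCL22 (742 ± 97.7 CPM against 12.3 ± 1.38 in M1, log2 fold change -5.92 ± 0.11), ALOX15, a lipoxygenase induced by interleukin 4 (-5.10; 15 counts in M1, ratio 0.0283, interval 0.0158 to 0.0471), LPL (-3.93), the signal inhibitor CISH (-3.61), TGM2 (-2.15) and CD209 (-1.59). MRC1, a common M2 marker, had too few counts to be tested.

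By list, 23 of 25 M1 markers were higher and 2 lower in M1, with the same counts adjusted over the list alone (median 3.61, adjusted p = 5.2e-112, and adjusted p = 4.6e-05 with an estimated correlation). Of the type I interferon genes 29 of 30 were higher (camera adjusted p = 6.7e-67, and adjusted p = 0.0062 with an estimated correlation), and of the antigen presentation genes 25 of 25 (7.7e-50, and adjusted p = 6.0e-04 with an estimated correlation), with the same counts adjusted over the list alone. Of 15 inflammasome genes 11 were higher and 1 lower, with 12 and 1 adjusted over the list alone (4.9e-15, and adjusted p = 6.0e-04 with an estimated correlation). Of 16 M2 markers, 11 were lower and 2 higher in M1, with 13 and 2 adjusted over the list alone (median -1.36, adjusted p = 5.6e-11, and adjusted p = 0.0060 with an estimated correlation). The 2 that were higher in M1 were the lectin CLEC10A (3.96) and the scavenger receptor CD163 (0.81, adjusted p = 7.1e-07). Of the lipid lists, 13 of 26 PPAR targets were lower and 3 higher, with 16 and 3 adjusted over the list alone (median -0.30, adjusted p = 0.00023, and adjusted p = 0.012 with an estimated correlation). PPARG, at 104 ± 20.5 CPM in M2, was lower in M1 by a log2 fold change of -1.85 ± 0.11. Markers of lipid-associated macrophages were lower in 15 of 22 and higher in 4 on both counts, with TREM2 at -2.80 (median -0.62, adjusted p = 7.3e-08, but adjusted p = 0.070 with an estimated correlation). Camera, which tests for a shared direction, did not call targets of LXR (adjusted p = 0.63), cholesterol synthesis and uptake (0.92), fatty acid synthesis (0.63) or fatty acid oxidation (0.62). Their members still differed over all genes, in both directions. In M1, 6 of 14 LXR targets were higher and 5 lower, and 3 of 26 cholesterol genes were higher and 7 lower. For fatty acid synthesis 5 of 20 were higher and 9 lower, and for fatty acid oxidation 6 of 25 were higher and 7 lower.

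In all, edgeR's quasi-likelihood test called 6489 genes between M1 and M2 in DMSO, 3296 higher and 3193 lower in M1, of which 1937 differed by at least 1 on the log2 scale. With library size as the only scaling, which moved the median of all genes by -0.13, the split was 2395 higher and 4532 lower.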

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

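The tests of library composition, precision, expression ceiling, PPARG level, GC content and the source of the interferon difference below were chosen after the results were seen, and the counts over other splits of the libraries were planned.

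By the test of the difference itself, 25 genes responded differently to MCHP in M1 and M2. The M1 minus M2 log2 differences were positive for CCL8 (1.01), ZNF618 (0.93), CCL1 (0.78), CD209 (0.77), XIRP1 (0.72), IFIT2 (0.71), CD83 (0.57), LGALS9 (0.54) and NFKBIZ (0.50). They were negative for HADHA (-0.48), TNFRSF21 (-0.57), SCARB1 (-0.65), TKTL1 (-0.69), SLC7A8 (-0.73), ADGRE3 (-0.85), FABP5 (-0.92), TLR4 (-0.99), PLIN2 (-1.02), FABP3 (-1.19) and AOC3 (-1.24). The other 5, not chosen as named genes, were negative too, from -0.48 for ACSL5 to -1.47 for the pseudogene RPL41P1, with MT-RNR2 and the pseudogenes MTCO1P12 and FTH1P23 between these. Of 100 splits drawn from 200, with the libraries regrouped within M1 and within M2, 10 gave at least 25 genes, the real one included. The highest other split gave 508 genes. It kept M1 as it was and exchanged the M2 labels as a whole, so its contrast adds both real responses and is no chance regrouping. All 9 others kept the M2 libraries with MCHP apart from those with DMSO, which points to the M2 response as the structure behind them. The highest count among splits that mixed these was 2. The 9 carry the M2 response into the contrast, and the splits that mixed the M2 libraries lose it. The splits therefore cannot decide about chance for this count, which stays open. Without M2 DMSO replicate 1 the count was 385, and it was 6 without M1 DMSO replicate 2 or M2 MCHP replicate 1.

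The same contrast set 16 gene lists apart by camera. Positive on the contrast were type I interferon response (adjusted p = 2.0e-09), NF-kB cytokines and chemokines (3.2e-08), dendritic cell markers (0.0037), M1 and M2 markers (0.0090 each), immediate early genes (0.014), and lysosome and matrix genes (0.025 each). Negative were PPAR targets (2.0e-09), mitochondrially encoded transcripts (4.2e-08), ribosomal proteins (0.0045), LXR targets (0.0065), fatty acid oxidation and glycolysis (0.0090 each), fatty acid synthesis (0.0092) and cell cycle (0.027). With an estimated correlation only the PPAR targets were called (adjusted p = 0.0032), and the others had adjusted p of 0.17 or higher. Of 100 splits 1, the real one, gave 16 or more lists, and the highest other gave 14. This leaves chance open, since splits that mixed the M2 libraries lost the M2 response and gave at most 9 lists. The 9 others that kept these apart gave 9 to 14, and 10 splits are too few for a share under 0.05. Without M2 DMSO replicate 1, fatty acid synthesis, cell cycle and glycolysis were no longer called (adjusted p = 0.077, 0.066 and 0.089). Calls were also lost for ribosomal proteins without M1 DMSO replicate 2 (0.12) or M2 MCHP replicate 2 (0.25), and for cell cycle without M2 MCHP replicate 2 (0.099) or M2 DMSO replicate 3 (0.14). The same held for matrix genes without M1 MCHP replicate 2 (0.095), M2 MCHP replicate 3 (0.13) or M2 DMSO replicate 2 (0.057), and for immediate early genes without M1 DMSO replicate 3 (0.051), M2 DMSO replicate 2 (0.18) or 3 (0.14). Lysosome genes lost the call without M1 MCHP replicate 1 (0.14), M1 DMSO replicate 2 (0.072) or 3 (0.074), or M2 DMSO replicate 2 or 3 (0.054 each). Without a filter on low counts M1 markers (0.057), M2 markers (0.22) and matrix genes (0.060) were not called, nor were cell cycle genes with GC offsets (0.054).

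PPAR target genes rose less with MCHP in M1 than in M2, with 22 of 26 members larger in M2. Lower precision in M1 with equal true changes is argued against by the slope of the M1 on the M2 changes over the list. The slope was 0.469 (95% bootstrap interval 0.0878 to 0.599 over 10000 resamples of the members), or 0.255 without FABP4, and did not reach 1. Corrected for error in the M2 changes it was 0.483 (0.0954 to 0.610), or 0.271 without FABP4 (0.0193 to 0.513). These intervals resample genes measured in the same libraries, so they leave out error between libraries. The median SE was 0.0861 in M1 and 0.0821 in M2. Both come from a fit in which all groups share the spread estimate, so they cannot compare the precision of M1 and M2. The correction for error in the M2 changes uses the SE of that fit and may be too small. Of the 14 members called higher in M2 only 1, ACSL1, was in M1 DMSO at or above its level in M2 with MCHP. Levels in M1 without MCHP had thus mostly not reached those in M2 with MCHP. This cannot decide about a ceiling, since the members were chosen for being high in M2 with MCHP. A lower ceiling particular to M1 cells would also leave this count low. Lower PPARG RNA remains a candidate explanation, with PPARG at -1.85 in M1 against M2 in DMSO, but receptor protein was not measured. PPARD went the other way and was called higher in M1. It held 7466 to 8488 counts per library in M1 DMSO and 4995 to 7456 in M2 DMSO. PPARG held 393 to 477 and 1523 to 2029. Receptor level and polarization cannot be told apart because they change together in this design. Other differences between M1 and M2 cells remain open and untested.

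M2 DMSO replicate 1 differed from its group more than any other library did. Its GC trend (Spearman rho of -0.577 across genes) could be part of this, but after each library's GC trend was removed the SD of its log2 deviations was still 0.218, above the 0.166 of the next library, so the trend is not the whole cause. For MCHP or RNA of treated cells in this library, its median absolute log2 deviation from replicates 2 and 3 was 0.208. The MCHP mean of 3 libraries lay at 0.108. Replicates 2 and 3, each against the other M2 DMSO libraries, gave 0.115 and 0.121. Each was set against a mean that includes replicate 1, so these values do not give the noise of an ordinary library. The value of 0.208 was above these too, but the GC trend was not removed here, so this cannot decide the point. How large a share MCHP or such RNA has stays open: FABP4 in this library lay 8.92%, PLIN2 4.49%, CD36 21.9%, FABP5 1.67%, TLR4 -0.707% and SHANK3 -23.3% of the way to the MCHP level. An earlier test, replaced after its result was seen, used the 92 genes that at least doubled or halved without this library. Over these it lay a median share of 0.347 of the way toward MCHP. The same test on replicates 2 and 3 gave 0.197 and 0.185. There too replicate 1 was part of the mean compared against, so these shares are not a clean control.

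The lower type I interferon genes with MCHP in M2 may come from M2 DMSO replicate 1 alone, since without it the list had an adjusted p of 0.75 and its median went from -0.18 to -0.01. In that library 27 of 30 members were higher than in replicates 2 and 3. The GC trend between libraries is argued against as the cause, since with GC offsets the adjusted p was 5.3e-04. No biological explanation was tested for this library's deviation or its higher interferon genes.

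For the other counts 10 splits exist per comparison, too few for a share under 0.05. In each of these the real split alone, 1 of 10, reached the real value: 13 genes in M1, 779 in M2 and 6489 between M1 and M2, with a highest other count of 0 each. The lists gave 11 in M1, 14 in M2 and 14 between M1 and M2, with highest others of 5, 8 and 11. For the 11 genes shared by both responses, 1 of 100 splits, the real one, was as large and the highest other was 0. This decides nothing, since M1 had no called gene in 98 of these splits and the 1 left besides the real one kept M1 as it was and exchanged the M2 labels as a whole.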

How the results depend on the processing

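GC offsets, quality weights, the M1 contrasts without M2 DMSO replicate 1, the paired settings, protein-coding genes only for single genes, and fits of 6 libraries for single and shared genes were chosen after the data were seen, and the others were planned. No named gene or list reversed its direction in a call. The count in M1 (13) was 76 without a filter, 5 with a replicate block, 55 by DESeq2, 207 with quality weights, 70 with GC offsets, 1 at a log2 change of at least 1, 287 in its own 6 libraries and 1 to 160 with a library left out, where 160 was without M2 DMSO replicate 1. The count in M2 (779) was 2733 with quality weights, 1594 with GC offsets, 50 at a log2 change of at least 1, 177 in its own 6 libraries, 1194 there without M2 DMSO replicate 1, and 386 to 1747 with a library left out. Without M2 DMSO replicate 1, 750 of the 779 were kept. The order of the M1 and M2 counts thus turned in the fits of 6 libraries (287 against 177), where each comparison had its own spread estimate. It did so only with M2 DMSO replicate 1 included, since without that library M2 had 1194. The difference (25) was 170 without a filter, 95 by DESeq2, 656 with quality weights, 130 with GC offsets, 6 at a log2 change of at least 1 and 6 to 385 with a library left out. The shared genes (11) were 47 without a filter and by DESeq2, 5 with a replicate block, 144 with quality weights, 56 with GC offsets, 0 at a log2 change of at least 1, 59 in fits of 6 libraries and 1 to 113 with a library left out. Between M1 and M2 (6489), only a log2 change of at least 1 moved the count past 1.5 times, to 1937. Lists called with an estimated correlation were 1 of 11 in M1 (1 as well without M2 DMSO replicate 1), 1 of 14 in M2, 1 of 16 for the difference and 9 of 14 between M1 and M2. The stricter log2 threshold lowers a count by construction, and otherwise the cause was not tested. Of called named genes, 1 of 13 in M1, 41 of 78 in M2, 6 of 20 for the difference and 153 of 159 between M1 and M2 kept the call under every alternative other than a log2 change of at least 1, and 0, 16, 2 and 101 with it as well. Of those not called, 21 of 50, 13 of 20, 33 of 52 and 2 of 4 were called under at least 1. With a replicate block the counts in M2, the difference and M1 against M2 were 692, 24 and 6387. Depth limits FABP4 in M1, with 6 counts in DMSO, and the marker MRC1.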

Other observations

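The tests in this part were all planned, apart from single genes in fits of 6 libraries. In M2, of 17 heat shock and metallothionein genes 3 fell, with the metallothionein MT2A (-0.74) among them, and 2 rose, with the chaperone HSPA8 (0.26) among them. Adjusted over the list alone 4 fell and 3 rose, and the list was not called by camera (adjusted p = 0.96). Of 16 genes of eicosanoid synthesis, ALOX5 (-0.68) and PTGS1 (-0.25) fell and PTGS2 rose, with 5 and 1 adjusted over the list alone (median -0.14, adjusted p = 0.014, but adjusted p = 0.097 with an estimated correlation). This list was no longer called without M2 MCHP replicate 3 (adjusted p = 0.055). CD74, the invariant chain, (-0.39) was among the 2 of 25 antigen presentation genes that fell, with the same count adjusted over the list alone (median -0.11, adjusted p = 0.0497, but adjusted p = 0.46 with an estimated correlation). The antigen presentation call was lost without M2 MCHP replicate 3 or M2 DMSO replicate 3 (0.25 each) and without a filter on low counts (0.056). Of 24 secreted factors with a role in exchange with adipose tissue, BMP2 (0.62) and ANGPTL4 rose and 5 fell, such as VEGFA (-0.24) and CCL2, with 4 and 8 adjusted over the list alone, and camera did not call the list (adjusted p = 0.27), although it called it lower without M2 DMSO replicate 1 (0.031). BMP2 was no longer called without M2 MCHP replicate 1 (0.083) or 3 (0.095), and VEGFA without M2 MCHP replicate 3 (0.081) or M2 DMSO replicate 3 (0.070). Of 8 monocyte markers CX3CR1 alone fell, also adjusted over the list alone (median -0.31, adjusted p = 0.025, but adjusted p = 0.13 with an estimated correlation). That call was lost without a filter on low counts (0.072) and without M2 DMSO replicate 1 (0.17) or 3 (0.054) or M2 MCHP replicate 2 (0.088). In a fit of the 6 M2 libraries alone HSPA8, PTGS1, PTGS2, BMP2, ANGPTL4, VEGFA and CCL2 were no longer called (0.058 to 0.15).

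In M1, 4 further lists were called by camera, none with a member called over all genes by edgeR's quasi-likelihood test. Cytosolic ribosomal proteins were lower (median -0.06, adjusted p = 0.0023, but adjusted p = 0.49 with an estimated correlation), and not without M1 DMSO replicate 2 (0.34). Cell cycle genes were lower (median -0.08, adjusted p = 0.0032, but adjusted p = 0.091 with an estimated correlation). Antigen presentation genes were lower (median -0.02, adjusted p = 0.020, but adjusted p = 0.47 with an estimated correlation), with 1 lower adjusted over the list alone. They were no longer called without M1 MCHP replicate 3 (0.098) or M1 DMSO replicate 1 (0.13) or 2 (0.077), or without a filter on low counts (0.0502). Genes of the p53 response were higher (median 0.06, adjusted p = 0.038, but adjusted p = 0.22 with an estimated correlation). That call was lost without M1 MCHP replicate 1 (0.097) or 3 (0.087) or M1 DMSO replicate 2 (0.058) or 3 (0.094).

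Between M1 and M2 in DMSO, 28 of 43 oxidative phosphorylation genes were lower in M1 and 1 was higher, with 29 and 1 adjusted over the list alone (median -0.36, adjusted p = 0.00023, but adjusted p = 0.33 with an estimated correlation). Of 36 cytosolic ribosomal protein genes 28 were lower and 1 was higher, with 31 and 1 adjusted over the list alone (median -0.40, adjusted p = 5.3e-05, but adjusted p = 0.43 with an estimated correlation).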
